A study of Homo sapiens and Mus musculus with 7 samples.

How the data were processed

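The deposited files give 1 value per gene for each of 7 libraries, prepared from Trizol-extracted total RNA with the TruSeq Stranded mRNA kit per the labels. Colon tissue of C57BL/6 mice with dextran sulfate sodium colitis gave 1 wild-type and 1 miR-7 deficient library. FHC human colonic epithelial cells treated with LPS gave 2 negative control, 2 miR-7 inhibitor and 1 erlotinib plus inhibitor library. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks and HTSeq without versions or roles, and list the mouse build mm10 for every sample. The build used for the human libraries is not given in the sources used here, nor whether strand was used in counting.

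The deposited values are in FPKM (fragment counts scaled to gene length and to the counted fragments of the library), a unit read from the values because the files name none. In the human libraries, values multiplied by the summed exon length in GENCODE 29 were whole multiples of 1 amount per library for 94.6% to 94.7% of the listed genes, within 0.01 of a fragment. That amount gave a depth of 17537675 counted fragments for control library 1, 17598429 for control library 2, 17876155 for inhibitor library 1, 16881896 for inhibitor library 2 and 16944726 for the erlotinib library. The files list only genes above 0, and genes missing from a library were set to 0. Of 30486 human identifiers, 24156 were named from the name table, 6215 from GENCODE 29 and 115 remained without a name. None of the 26392 mouse identifiers could be named from the tables used here.

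FHC libraries were compared with limma 3.58.1 in R 4.3.3. Limma-trend was fitted to log2(FPKM + 1) of genes with at least 1 FPKM in at least 2 of the 5 libraries, with group as the only term and no replicate block. All p-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. The fit had 2 residual degrees of freedom, and 2.93 prior degrees of freedom were added by empirical Bayes. The erlotinib library adds nothing to the estimate of spread and was assumed to vary like the other FHC libraries. The scale understates fold changes of genes near or below 1 FPKM. On simulated data with 200 changed genes, log2 changes of 1 were recovered in 74.9% of cases for inhibitor against control and in 63.1% for erlotinib plus inhibitor against inhibitor, changes of 2 in 95.4% and 93.1%, and changes of 0.5 in none. These shares hold for 200 genes changed by the same amount, with spreads drawn from the fitted prior. In the data, 136 genes differed at least 2-fold between erlotinib plus inhibitor and inhibitor, and 0 were called. The absence of calls thus does not show that 2-fold changes were few.

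Gene lists were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation and with fry beside it, for lists with at least 3 tested members. With an estimated correlation, camera rests on the residual degrees of freedom of the fit, 2 here. Few lists could pass on so few, whatever the correlation between their members. Fry also rests on these degrees of freedom. Fits with a library left out had fewer still, so a failure to pass there decides little. The lists held reported miR-7 targets, EGFR family receptors and ligands, ERK-induced transcripts, NF-kB-induced genes (cytokines and others), interferon-induced genes, cell cycle genes, p53-induced genes, cholesterol synthesis, the unfolded protein response, hypoxia and glycolysis, tight junctions, epithelial (general and intestinal), mesenchymal and goblet cell genes, ribosomal proteins and mitochondrial transcripts. The lists, the main tests, most of the alternatives and the rule for named genes were fixed before the data were examined. The rule named genes past the threshold whose library values did not overlap between groups and whose mean was at least 1 FPKM, up to 10 per direction. Where fewer passed, it named those with the smallest p-values, up to 10 per direction, said not to pass. In the mouse libraries it ranked genes with at least 5 FPKM by log2 ratio, of which 2 identifiers per direction are given. Genes outside the rule and the lists were chosen after their values were seen.

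Sites for miR-7-5p were searched in 3' UTRs of GENCODE 29. The difference of medians between genes with and without a site was set against 10000 random sets matched on 3' UTR length and expression in 10 bins each. The correlation of the inhibitor and erlotinib changes across genes was compared with 200 simulations of unchanged groups sharing the same libraries. Mouse genes with at least 1 FPKM in either library were compared by log2((deficient FPKM + 1) / (wild-type FPKM + 1)), without a test. Sequence shared between genes was counted in words of 100 bases of their transcripts. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

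Alternatives were quantile normalization, no filter on low values, a mean of at least 5 FPKM, a pseudocount of 0.1, robust empirical Bayes, each control and inhibitor library left out in turn, only the 4 control and inhibitor libraries, and these with a replicate block. After seeing the data, 3 more were added: limma-voom on recovered fragments of genes with at least 10 fragments in 2 libraries, protein-coding genes only, and a minimum of 1 FPKM in 1 library. Mouse gene lists and the correlation of mouse with FHC changes were not run, because the mouse identifiers could not be named. Methods that need deposited counts were not used here.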

Results

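RNA sequencing was deposited for 7 libraries from 2 systems in which the microRNA miR-7 was reduced. The first was colon tissue of C57BL/6 mice aged 8 to 10 weeks with colitis produced by dextran sulfate sodium, with 1 wild-type and 1 miR-7 deficient library. The second was FHC, a human colonic epithelial cell line treated with lipopolysaccharide (LPS), a bacterial cell wall component that triggers inflammatory signalling. It had 2 libraries transfected with a control oligonucleotide for the miR-7 inhibitor, 2 with the inhibitor itself, and 1 with the inhibitor plus erlotinib, a drug that blocks the kinase of the epidermal growth factor receptor (EGFR). The depth recovered from the deposited values was 15514211 counted fragments for the wild-type and 15965586 for the deficient mouse library, and 16881896 to 17876155 for the FHC libraries. The labels do not say whether libraries with the same treatment came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

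The comparison of inhibitor with control libraries asked which FHC transcripts differed when miR-7 was blocked. EGFR, a reported miR-7 target, had 17.4 ± 0.841 FPKM (SD, n = 2) in the control and 17.6 ± 1.04 FPKM (SD, n = 2) in the inhibitor libraries, a log2 difference of 0.01 with a 95% interval of -0.17 to 0.19. HNRNPK, whose intron holds a miR-7 locus, had 153 ± 2.99 and 155 ± 5.72 FPKM (SD, n = 2 each), a log2 difference of 0.01 (SE 0.05). The miR-7 loci MIR7-1, MIR7-2 and MIR7-3HG, the miR-7 sponge transcript CDR1 and the goblet cell peptide TFF3 were not listed in any FHC library. These libraries, made with an mRNA kit, did not measure the level of miR-7 itself. Limma-trend called 0 of 12774 genes (smallest adjusted p = 0.291); 412 genes, or 3.23%, had an unadjusted p under 0.05, 202 of them higher and 210 lower with the inhibitor. With 1 library left out this number ran from 332 to 664, the latter without inhibitor library 1 and divided into 274 higher and 390 lower. Limma-voom on recovered fragments also called 0 genes, with 266 at an unadjusted p under 0.05.

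None of the genes with the smallest p-values passed the test, and most were short RNA genes or pseudogenes resting on few fragments. On the higher side, the microRNA gene MIR3192 had 2.22 and 2.21 FPKM in the control libraries against 5.81 and 6.15 FPKM with the inhibitor, the latter resting on 8 fragments in each of the 2 libraries. SNORA71C, SNORA33, SNORD83A, MIR186, RNU6-1099P, RPL39P15, MIX23P3, SDHDP6 and CD63-AS1 followed. On the lower side, MIR647 had 17.8 and 16.6 against 9.32 and 9.87 FPKM, followed by SNORD6, MIR200A, MIR93, MIR4312, SNORA60, RNA5SP323, ECI1-AS1, RPS29P16 and RPL28P2. Among protein-coding genes, singled out after their values were seen, the calcium-binding protein gene S100A4 had 88.5 ± 3.51 against 106 ± 6.60 FPKM (SD, n = 2 each). The fibrinogen chain genes FGA (9.27 ± 0.226 against 10.9 ± 0.329 FPKM) and FGG (6.09 ± 0.298 against 7.60 ± 0.511 FPKM) and the mucin glycosyltransferase gene GCNT3 (7.40 ± 0.348 against 9.27 ± 0.693 FPKM) were also higher, all with an adjusted p of 1 (SD, n = 2 each, limma-trend). Lower with the inhibitor, also with an adjusted p of 1, were TSPO2, a cholesterol-binding protein gene (3.75 ± 0.335 against 2.62 ± 0.0588 FPKM), the cell cycle gene CDCA3 (6.94 ± 0.188 against 5.64 ± 0.139 FPKM) and the AP-1 transcription factor gene JUN (27.3 ± 0.772 against 23.3 ± 1.06 FPKM). With protein-coding genes alone, limma-trend called 0, and 98 genes were higher and 100 lower at an unadjusted p under 0.05.

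None of the 16 gene lists with enough measured members passed camera in this comparison, and no member of any list passed when adjusted over the list alone. With a replicate block camera passed 3, the cholesterol synthesis, hypoxia and ribosomal protein genes, but none of them with an estimated correlation. Camera passed 4 lists without control library 1, 2 without control library 2 and 4 without inhibitor library 2, none of which passed with an estimated correlation (adjusted p = 0.785 to 0.986). Of 18 measured genes reported as miR-7 targets, 9 were higher and 9 lower with the inhibitor (median log2 difference 0.0013, mean -0.0075, adjusted p = 0.851). Their median turned negative whichever library was left out (-0.0175 to -0.0103). The members farthest from 0 were TNK2 (-0.13, SE 0.11), RELA (-0.11, SE 0.07) and UBE2A (0.10, SE 0.10). Of the EGFR family receptors and ligands, 5 of 6 were lower, led by HBEGF (-0.25, SE 0.10) and TGFA (-0.22, SE 0.09). Their median was -0.03 (-0.12 to -0.04 with 1 library left out), with an adjusted p of 0.21 by camera and of 0.0441 by fry, which tests the list without comparing it with other genes. With an estimated correlation the adjusted p was 0.983, and that of fry ran from 0.00998 to 0.969 over the alternatives, with none under 0.05 when a library was left out. Fry rests on the residual degrees of freedom, fewer in those fits, so its failure there decides little. ERK-induced transcripts divided 11 to 11 (adjusted p = 0.531), NF-kB-induced genes were lower in 8 of 13 (adjusted p = 0.673) and interferon-induced genes in 19 of 24 (adjusted p = 0.246). The lowest camera values were an adjusted p of 0.114 for ribosomal protein genes, 22 of 28 higher with a median of 0.03, and of 0.123 for cholesterol synthesis genes, 15 of 19 higher with a median of 0.05. With 1 library left out the ribosomal median ran from -0.03 (without inhibitor library 1) to 0.08 and the cholesterol median from -0.0093 (without control library 1) to 0.12, and after quantile normalization the ribosomal median was -0.0070 (adjusted p = 0.889). The median and the direction of the test had opposite signs for the reported targets and for the tight junction genes (10 of 15 lower, adjusted p = 0.997). The median and the mean had opposite signs for the mitochondrial transcripts (7 of 13 higher, median 0.0062, mean -0.04, adjusted p = 0.851), whose median also changed sign with the library left out.

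Sites for miR-7-5p in 3' UTRs were read as GTCTTCC, the 7-base match to the seed, or GTCTTCCA, the 8-base match. Of 10389 tested genes with an annotated 3' UTR, 1430 carried either site. Their median log2 difference exceeded that of the other genes by 0.0065, at the 99.8th percentile of 10000 sets matched on 3' UTR length and expression. The 460 genes with the 8-base match exceeded the others by 0.013, above all of the matched sets. The same differences of medians were 0.0029 and 0.0081 between the 2 control libraries and 0.0093 and 0.026 between the 2 inhibitor libraries (second library minus first). The shift with the inhibitor lay between these 2 for either site and for the 8-base match. That ranking decides little, since these medians are unmatched and single libraries vary more than 2-library means. Mean differences from matched genes were -0.0067 between the control and -0.015 between the inhibitor libraries for the 7-base site, against 0.0040 with the inhibitor. For the 8-base site they were 0.0028 and -0.0025, against 0.00998 with the inhibitor. For genes with either site, the difference of medians lay at the 82.4th percentile without control library 2 and at the 5.3rd without inhibitor library 1. The 8-base match alone was not examined with a library left out. Between erlotinib plus inhibitor and inhibitor alone, where both groups carried the inhibitor, genes with either site also lay at the 99.8th percentile of their matched sets (difference of medians -0.03, matched sets -0.05 on average). For either site, such a percentile thus arose without a contrast in miR-7 inhibition. For the 8-base match it did not, as those genes lay at the 76.8th percentile in this comparison.

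The comparison of erlotinib plus inhibitor with inhibitor alone asked what blocking the EGFR kinase did to cells in which miR-7 was inhibited. Transcripts induced by ERK, the kinase downstream of EGFR, fell as a group in the erlotinib library: 17 of 22 measured members were lower, with a median log2 change of -0.30 (camera adjusted p = 9.19e-06, fry adjusted p = 0.00332). The adjusted p was 0.504 with an estimated correlation between genes. With 1 library left out the median ran from -0.334 to -0.281. Fry did not pass in those fits, but they had fewer residual degrees of freedom, so this decides little. No member passed over all genes, and 11, all lower, passed when adjusted over the list alone. The ERK phosphatase gene DUSP6 had 8.24 FPKM against 17.0 ± 1.55 FPKM (SD, n = 2), the immediate early transcription factor gene EGR1 6.09 against 11.6 ± 0.736 FPKM, PHLDA1 5.62 against 10.1 ± 0.434 FPKM and ETV5, an ETS family transcription factor gene, 2.60 against 4.23 ± 0.557 FPKM. The cyclin gene CCND1 had 85.8 against 114 ± 8.75 FPKM, whereas FOS had 13.0 against 10.8 ± 1.55 FPKM. EGFR itself had 13.5 FPKM against 17.6 ± 1.04 FPKM, a log2 change of -0.36 (SE 0.09) that did not pass (adjusted p = 0.264).

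**Figure D1:**
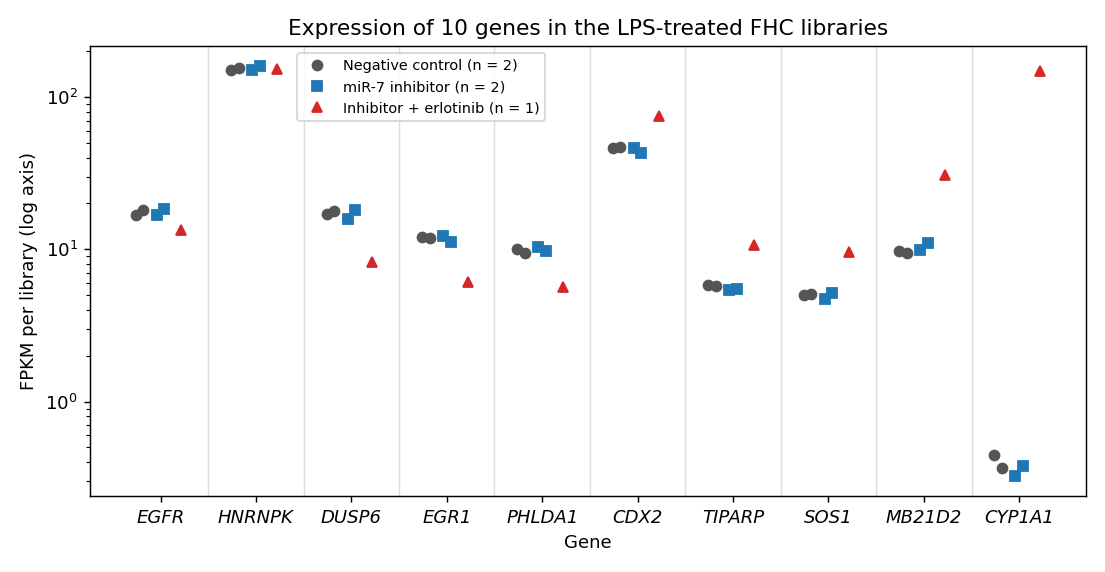
FPKM per library on a log axis for 10 genes in LPS-treated FHC cells, with circles for the control, squares for the inhibitor and triangles for the erlotinib plus inhibitor library. DUSP6, EGR1 and PHLDA1 had 8.24, 6.09 and 5.62 FPKM in the erlotinib library, below all of the other libraries, and CYP1A1 had 147 FPKM against at most 0.448 elsewhere.

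Cholesterol synthesis genes rose as a group, 15 of 19 higher with a median of 0.22 (camera adjusted p = 3.92e-04), and the adjusted p was 0.563 with an estimated correlation. Their largest changes were in DHCR7 (24.97 against 19.2 ± 0.906 FPKM) and INSIG1 (13.6 against 10.6 ± 0.150 FPKM). Interferon-induced genes rose, 19 of 24 higher with a median of 0.16 (adjusted p = 5.03e-03, and adjusted p = 0.563 with an estimated correlation), among them IFIT3 at 11.2 against 8.44 ± 0.634 FPKM. Epithelial genes, a list of general and intestinal ones, rose, 12 of 15 higher with a median of 0.09 (adjusted p = 5.03e-03, and adjusted p = 0.563 with an estimated correlation). The general members EPCAM, KRT8 and KRT18 had log2 changes of 0.09, 0.02 and 0.05. The intestinal transcription factor gene CDX2 had 74.9 against 44.5 ± 2.58 FPKM, the keratin gene KRT20 5.12 against 2.40 ± 0.516 FPKM, and CDH1, which encodes E-cadherin, 2.12 against 2.72 ± 0.156 FPKM. Cell cycle and replication genes rose, 17 of 22 higher with a median of 0.11 (adjusted p = 9.29e-03, and adjusted p = 0.694 with an estimated correlation), and so did ribosomal protein genes, 21 of 28 higher with a median of 0.05 (adjusted p = 3.37e-02, and adjusted p = 0.873 with an estimated correlation). Estimated correlations between members, the same in every comparison, were 0.879 for ribosomal protein, 0.269 for cell cycle and 0.136 for cholesterol synthesis genes. They were 0.0514 for interferon-induced and -0.0137 for epithelial genes. Where they exceed the preset of 0.01, most for ribosomal protein genes, the camera p-value at the preset may be too small. For none of these 5 lists did fry pass with all libraries as reported (adjusted p = 0.111 to 0.648), and among the alternatives it passed only the epithelial genes after quantile normalization (adjusted p = 0.0327). Adjusted over the list alone, 2 epithelial genes passed and 0 of the other 4 lists, against 0 over all genes by limma-trend. Without inhibitor library 1 the interferon-induced genes (adjusted p = 0.0835) and the cell cycle genes (adjusted p = 0.396) no longer passed. Without inhibitor library 2 the ribosomal protein genes did not (median -0.0020, adjusted p = 0.816), nor did they with no filter on low values (adjusted p = 0.119) or at a mean of 5 FPKM or more (adjusted p = 0.118). After quantile normalization the epithelial (adjusted p = 0.0666), cell cycle (adjusted p = 0.152) and ribosomal protein genes (adjusted p = 0.587) did not.

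The other lists did not pass camera on limma-trend with all libraries. By voom the NF-kB-induced genes and the hypoxia genes passed (adjusted p = 0.0267 each, and adjusted p = 0.401 with an estimated correlation). Without inhibitor library 2 the unfolded protein response genes (adjusted p = 0.00651) and the hypoxia genes (adjusted p = 0.0129) passed, each with an adjusted p of 0.833 with an estimated correlation. The estimated correlation over all libraries was 0.83 for the unfolded protein response and 0.422 for the hypoxia genes, also above the preset. Adjusted over the list alone, 2 NF-kB-induced genes and 1 gene each among reported miR-7 targets, p53-induced genes and mitochondrial transcripts passed, all lower. NF-kB-induced genes were lower in 10 of 13 members (median -0.13, adjusted p = 0.124). The median was -0.06 without inhibitor library 2 and -0.04 with no filter on low values. The neutrophil-attracting chemokine gene CXCL1 had 0.455 against 1.64 ± 0.00367 FPKM, and the prostaglandin synthase gene PTGS2 8.27 against 13.6 ± 1.76 FPKM. CXCL1, CXCL2 (log2 change -0.08) and CXCL3 (0.11) were the only cytokine genes of the list that could be tested. The others, such as CXCL8, IL6 and TNF, lay below the minimum. Reported miR-7 targets were lower in 10 of 18 (median -0.04, adjusted p = 0.842), with IRS1, an insulin receptor substrate gene, at 7.37 against 10.7 ± 0.233 FPKM. The EGFR family receptors and ligands divided 3 to 3 (median 0.02, mean -0.04, with the test on the lower side, adjusted p = 0.842). Hypoxia and glycolysis genes were lower in 11 of 13 (adjusted p = 0.165), unfolded protein response genes higher in 11 of 14 (adjusted p = 0.165), p53-induced genes lower in 9 of 16 (adjusted p = 0.372), mesenchymal genes lower in 4 of 5 (adjusted p = 0.198) and goblet cell genes 3 of 6 (adjusted p = 0.64). Tight junction genes (median 0.00014) and mitochondrial transcripts (median -0.02, mean 0.04, with the test on the lower side) each had an adjusted p of 0.842. Of the blood and immune cell genes only CSF1R was measured above the minimum, at 1.34 against 1.03 ± 0.0416 FPKM.

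**Figure D2:**
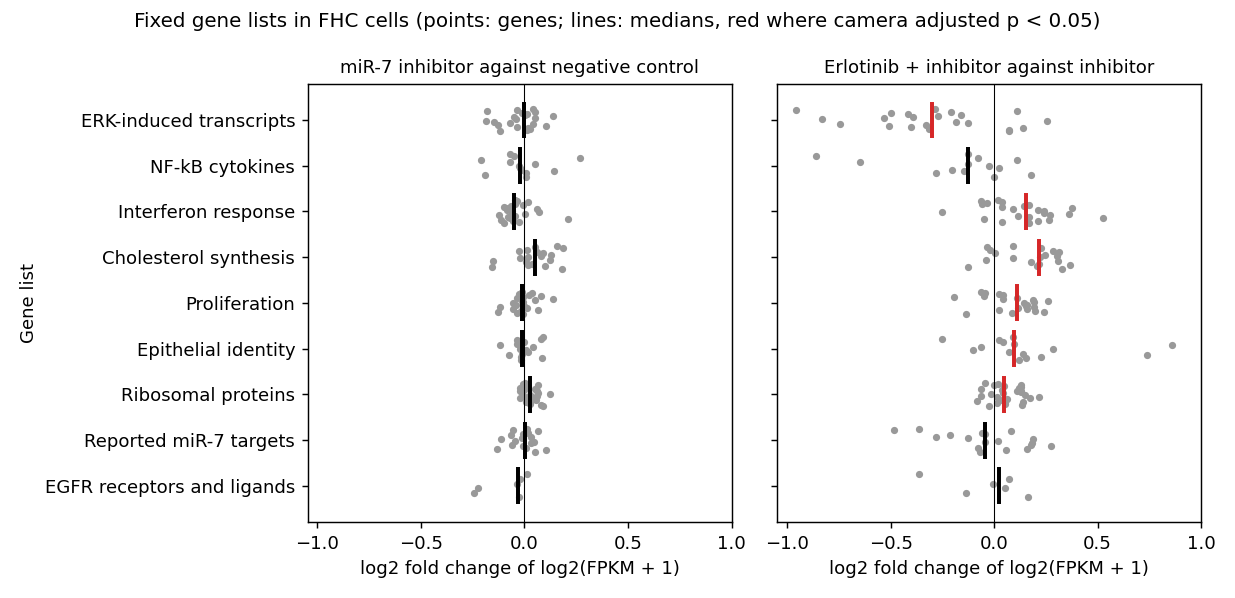
Log2 fold changes of the measured members of 9 gene lists (points) and their medians (lines, red where the camera adjusted p was under 0.05) for inhibitor against control on the left and erlotinib plus inhibitor against inhibitor on the right. The median of the ERK-induced transcripts was -0.30 and that of the cholesterol synthesis genes 0.22 in the right panel, while no list passed in the left panel.

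Gene by gene, limma-trend called 0 of 12774 genes with erlotinib (smallest adjusted p = 0.0686), 1707 genes, or 13.4%, had an unadjusted p under 0.05, 725 higher and 982 lower (1107 to 1820 in all with 1 library left out), and limma-voom on recovered fragments called 85 genes, 36 higher and 49 lower. The smallest p-values on the higher side belonged to the spliceosome assembly gene SMN1 (15.9 against 4.16 ± 0.181 FPKM; log2 change 1.71, SE 0.08, adjusted p = 0.0686), 77.5% of whose sequence is shared with a gene elsewhere, and to MB21D2 (30.9 against 10.5 ± 0.763 FPKM; log2 change 1.47, SE 0.08). They were followed by TIPARP, SOS1, CDX2, LINC00543, the ribosomal pseudogenes RPL14P1 and RPL22P1, SNORD6 and SNORD100. SOS1, a RAS exchange factor gene downstream of EGFR, had 9.62 against 4.92 ± 0.313 FPKM. The smallest on the lower side were those of SNORD73B, MIR23B, EGR1, DUSP6, the perforin gene PRF1 (7.59 against 16.0 ± 1.33 FPKM), S100A2, RPL9P7, PHLDA1, the Wnt pathway antagonist gene NKD1 (3.19 against 5.80 ± 0.0664 FPKM) and MT-ND6. Genes called by voom, chosen here after their values were seen, also included the kinase gene PIM1, LGALS3, REG1A and HSPA8 on the higher side and ITGA2, TGM2, TGFBR2, BAMBI, FGF20, TCF7L2 and LGR4 on the lower side. The erlotinib library stood alone in its group and was assumed to vary like the others, so erlotinib cannot be separated from whatever else set this library apart. Counts of called genes ran from 0 to 241 across settings.

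The largest difference, singled out after the values were seen, was in CYP1A1 (ENSG00000140465; chromosome 15, 74719542 to 74725610, minus strand, GRCh38), a cytochrome P450 gene induced through the aryl hydrocarbon receptor. It had 147 FPKM, from 8554 fragments, in the erlotinib library and 0.326 to 0.448 FPKM in the others, so that it missed the requirement of 1 FPKM in 2 libraries. Limma-voom gave a log2 change of 8.67 (SE 0.26, adjusted p = 4.31e-08). Of 12 tested genes within 250 kb, 10 were higher in the erlotinib library than in all 4 others, against 27% of all tested genes. EDC3, which encodes an mRNA decapping factor, had 16.2 FPKM against 7.74 to 8.92 FPKM in the others, the SRC-inhibiting kinase gene CSK 19.2 against 12.1 to 12.8 FPKM and the ribonuclease P subunit gene RPP25 33.2 against 22.5 to 23.5 FPKM. All 3 were called by voom. The median log2 change of the 12 genes was 0.23, at the 99.7th percentile of 10000 runs of 12 consecutive tested genes elsewhere.

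**Figure D3:**
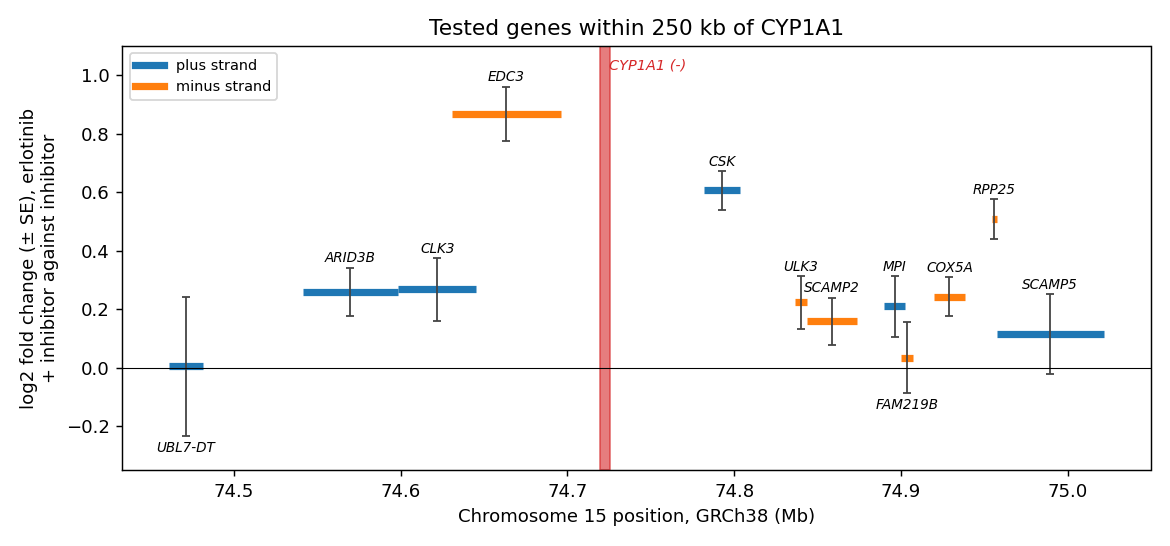
Log2 fold change (thick lines spanning each gene, blue for the plus and orange for the minus strand, with SE from limma-trend) of the 12 tested genes within 250 kb of CYP1A1 on chromosome 15 (GRCh38), erlotinib plus inhibitor against inhibitor. EDC3 and CSK, the nearest tested genes on either side, had log2 changes of 0.87 and 0.61, and UBL7-DT one of 0.0053.

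The comparison of the erlotinib library with the control libraries uses the same erlotinib library as the comparison with the inhibitor, so these comparisons are not independent. ERK-induced transcripts were lower in 19 of 22 members (median -0.31, camera adjusted p = 2.43e-07, and adjusted p = 0.397 with an estimated correlation), and cholesterol synthesis genes higher in 17 of 19 (median 0.25, adjusted p = 5.32e-06, and adjusted p = 0.52 with an estimated correlation). Ribosomal protein, epithelial, cell cycle and interferon-induced genes passed on the higher side (adjusted p = 6.47e-04, 3.27e-03, 1.27e-02 and 3.88e-02, and adjusted p = 0.76, 0.52, 0.661 and 0.554 with an estimated correlation). NF-kB-induced genes passed on the lower side, 10 of 13 with a median of -0.07 (adjusted p = 4.21e-02, and adjusted p = 0.52 with an estimated correlation). Only the ERK-induced and cholesterol synthesis genes passed camera in every alternative without an estimated correlation. The NF-kB-induced genes did not pass without control library 2, and their median was -0.04 without control library 1. Nor did they pass after quantile normalization (adjusted p = 0.0917), at a mean of 5 FPKM or more (adjusted p = 0.0548) or with no filter on low values (adjusted p = 0.149). Interferon-induced genes did not pass without control library 1 (adjusted p = 0.173), by voom (adjusted p = 0.0792) or at a mean of 5 FPKM or more (adjusted p = 0.316), nor cell cycle genes in 2 of these (adjusted p = 0.0622 without control library 1 and 0.0548 at a mean of 5 FPKM or more). After quantile normalization the cell cycle (adjusted p = 0.207), epithelial (adjusted p = 0.108) and ribosomal protein genes (adjusted p = 0.542) did not. By gene, limma-trend called 0 (smallest adjusted p = 0.0584), with 1696 at an unadjusted p under 0.05 (894 and 896 without control library 1 or 2), and limma-voom called 88. Across genes, the changes with the inhibitor and those with erlotinib had a Pearson correlation of -0.288 and a Spearman correlation of -0.237. Both comparisons use the inhibitor libraries with opposite signs, and unchanged groups simulated with the same libraries gave a Pearson correlation of -0.41. The observed Pearson correlation ran from -0.498 to -0.216 with 1 library left out. It was 0.0772 and 0.0714 when the comparisons shared no inhibitor library. The covariance was -0.0123 against -0.0161 in the simulation, a difference of 0.0038. The simulation drew each library independently, whereas deviations of control and inhibitor libraries with the same number correlated at 0.142 across genes. Such shared deviations can raise the covariance, also where no inhibitor library is shared. The distance from the simulation and the positive values thus decide nothing.

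In the mouse colon the question was which transcripts differed with miR-7 deficiency during colitis, with no replicate of either genotype. Of 14498 genes at 1 FPKM or more in either library, 605 were at least 2-fold higher and 1300 at least 2-fold lower in the miR-7 deficient library, on the scale of log2(FPKM + 1). The gene ENSMUSG00000026531 had 2.90 FPKM in the wild-type and 683 FPKM in the deficient library, and ENSMUSG00000082062 was listed only in the deficient library, at 210.0 FPKM. In the other direction, ENSMUSG00000040809 had 53 and 0.192 FPKM, and ENSMUSG00000095866 was listed only in the wild-type library, at 61.1 FPKM. Among the 562 genes at 100 FPKM or more in either library, 41 were at least 2-fold higher and 34 at least 2-fold lower in the deficient one. The log2 ratio had a median of -0.02 and an SD of 0.716 across genes, and the libraries correlated across genes with Pearson's r of 0.914 and Spearman's rho of 0.889. These numbers describe 2 libraries, and genes are given by identifier because the tables used here pair none of the mouse identifiers with a name.

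**Figure D4:**
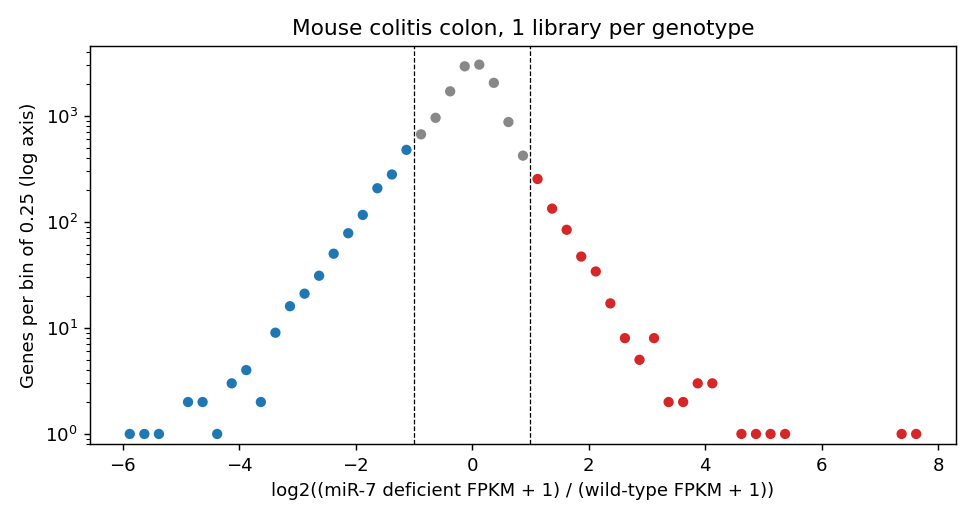
Number of genes per bin of log2((miR-7 deficient FPKM + 1) / (wild-type FPKM + 1)) in the 2 mouse colitis libraries, 1 point per bin of 0.25 on a log axis, red where at least 2-fold higher and blue where at least 2-fold lower. The 1300 genes on the lower side outnumber the 605 on the higher side, and the median of all 14498 genes lies at -0.02.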

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

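The voom, protein-coding and 1-library alternatives were chosen after the data were seen, and the others were planned. The 8 values that answer a comparison gave 102 alternatives, of which 73 stayed near the reported value, for counts within 1.5 times it. For the single genes and lists named, 1396 of 1516 alternatives kept direction and side of the threshold. Of the others, 78 newly passed, 14 no longer passed and 28 changed sign. These shares do not measure robustness, since some alternatives could not change a direction. Robust empirical Bayes left the fold changes as they were. So did fits of only the control and inhibitor libraries, for inhibitor against control. Leaving out a control library did so for erlotinib plus inhibitor against inhibitor. Fits with a library left out had fewer residual degrees of freedom, so staying above the threshold there decides little. No alternative called a gene for inhibitor against control by limma.

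Genes called for erlotinib plus inhibitor against inhibitor, 0 as reported, numbered 241 with no filter on low values, 28 at a mean of 5 FPKM or more, 85 by voom, 24 among protein-coding genes and 1 (CYP1A1) with 1 FPKM in 1 library. Against the control these counts were 284, 28, 88, 17 and 1, and 2 under robust empirical Bayes. Of the 241, 197 lay under 1 FPKM in every library. Voom shared 21 genes with the 5 FPKM filter. The cause was not tested. Leaving out any library called 0 genes in all 3 comparisons.

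For inhibitor against control, fry passed 1 gene list (EGFR family receptors and ligands), and leaving out 1 library passed 0 to 4. A replicate block called 0 genes, with 712 at an unadjusted p under 0.05, and passed 3 lists. These were cholesterol synthesis, hypoxia and ribosomal protein genes, with an adjusted p of 0.833, 0.833 and 0.914 with an estimated correlation and of 0.647, 0.36 and 0.813 by fry. Deviations of libraries with the same number correlated across genes at 0.142, and at 0.433 over protein-coding genes, but there were only 2 pairs, and the labels tie no culture or day to a number. The mean chi-square per gene (1 for counting noise alone) was 2.29 and 2.62 between control and inhibitor libraries of the same number. It was 3.44 between the control and 5.66 between the inhibitor libraries. Library number thus separated these libraries more than the inhibitor did, and the fit without a block keeps that difference in its spread. For erlotinib plus inhibitor against inhibitor, 6 lists passed as reported, 0 with an estimated correlation, 1 by fry (ERK-induced transcripts) and 3 after quantile normalization (ERK-induced, interferon-induced and cholesterol synthesis genes). By voom 8 passed, and 4 to 7 with 1 library left out. The cause was not tested.

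The correlation of the inhibitor and erlotinib changes was -0.182 at a mean of 5 FPKM or more, and -0.498 to -0.216 with 1 library left out. It turned to 0.0772 and 0.0714 when the comparisons shared no inhibitor library. By construction this removes the part due to shared inhibitor libraries, but not a part due to deviations common to libraries with the same number. The shift of genes with either miR-7 site was 0.0016 to 0.0080 with 1 library left out, inside the matched sets without control library 2 (0.0080) and without inhibitor library 1 (0.0074).

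Without filter, and at a mean of 5 FPKM or more, the median of the EGFR family list with erlotinib was -0.0054 in place of 0.02. With 1 library left out it ran from -0.0256 to 0.077. That of reported miR-7 targets ran from -0.0175 to -0.0103 with the inhibitor and from -0.0527 to 0.0105 with erlotinib, and that of ribosomal protein genes with erlotinib from -0.0020 to 0.115. With the inhibitor, the median of ribosomal protein genes ran from -0.0308 to 0.0841, of cholesterol synthesis genes from -0.0093 to 0.117 and of mitochondrial transcripts from -0.0267 to 0.0133. With erlotinib, that of tight junction genes ran from -0.0154 to 0.000141 and of mitochondrial transcripts from -0.0248 to 0.005. After quantile normalization the ribosomal and mitochondrial medians with the inhibitor were -0.00699 and -0.011, and the tight junction and mitochondrial medians with erlotinib -0.0232 and 1.78e-15, the last being 0 within machine precision. At a mean of 5 FPKM or more the tight junction median was -0.0148. EGFR ran from -0.0456 to 0.0689 with the inhibitor and ERBB2 from -0.0191 to 0.164 with erlotinib. HNRNPK ran from -0.0261 to 0.0489 with the inhibitor, from -0.0579 to 0.0172 for erlotinib plus inhibitor against inhibitor and from -0.0287 to 0.0108 against control. The cause was not tested.

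The 1905 mouse genes at least 2-fold different became 3028 with a pseudocount of 0.1 and 520 with one of 5, which by construction widens or narrows ratios at low values, and 1014 among genes with 5 FPKM or more, where fewer genes were compared. Count-based alternatives, mouse gene lists and the correlation of mouse with FHC changes were not run.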

Other observations

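All tests of explanations in this part were chosen after the results they address were seen. Among colonic genes outside the comparisons, the stem cell receptor gene LGR5 had 50.7 to 53.7 FPKM and the epithelial adhesion gene EPCAM 240.4 to 286 FPKM across the 5 FHC libraries. The mucin gene MUC2 had 0.0373 to 0.106 FPKM and the mesenchymal gene VIM 0.252 to 0.553 FPKM. Of the LPS receptor genes, TLR4 had 7.37 to 10.4 FPKM, while its partners LY96 and CD14 had at most 0.293 and 0.0313 FPKM. The LPS-inducible CXCL8 and IL6 had at most 0.925 and 0.192 FPKM. A library without LPS was not used here, so no response to it was measured.

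Several stress and metabolic genes differed within a treatment. The glutathione-degrading CHAC1 had 14.4 and 28.1 FPKM in the control and 15.6 and 24.3 FPKM in the inhibitor libraries, and the serine synthesis gene PSAT1 96.6 and 147, then 98.1 and 140.1 FPKM. The hypoxia-induced NDRG1 had 8.62 and 4.32, then 11.3 and 5.14 FPKM, and PFKFB4, a regulator of glycolysis, 4.32 and 1.95, then 5.30 and 2.11 FPKM. LINC00543, a long noncoding RNA gene, had 9.12 FPKM with erlotinib against 3.85 to 4.85 FPKM in the others.

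CYP1A1 had 147 FPKM in the erlotinib library and under 0.5 FPKM elsewhere. RNA of another cell type should bring other abundant transcripts, but 1 gene, CYP1A1 itself, reached 10 FPKM there while staying under 1 FPKM in the other libraries. A small share of such RNA, or a cell type with transcripts like those of FHC, would not show in this count. Aryl hydrocarbon receptor activity in that culture may account for it and stays open: 6 of 7 other genes of a list of its targets were higher there than in all 4 others, as were 27% of tested genes, but 4 of the 7 lay below the minimum for testing and the list was written after 3 of the 7 had been seen. Of the 4 unseen genes, NQO1 (130 against 93.1 to 108 FPKM) alone was expressed highly enough to be tested, and AHRR, UGT1A6 and CYP1A2 rested on 58, 57 and 2 fragments. Erlotinib and this culture cannot be told apart as the source, since there was 1 erlotinib library.

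Some genes with near-identical copies were higher in inhibitor library 2, in the erlotinib library or in both than in the other FHC libraries. Fragments of copied sequence assigned differently in these libraries may explain those higher in both: 7 of 15 genes at least 2-fold higher shared sequence with a gene elsewhere, and 7 of 7 with at least 50 fragments, against 2.4% of tested genes with as many fragments. Of genes higher in 1 library alone and at 1 FPKM or more in it, 7 of 63 shared sequence for inhibitor library 2 (1 of 3 with 50 fragments, U2AF1L5) and 8 of 54 for the erlotinib library (2 of 9). For EIF3C, CCZ1B, U2AF1L5, GPR89A and SMN1 the annotated copy lost at most 9.47% of what the gene gained. For CCZ1B and GPR89A this argues against a move of counted fragments from the copy. The copies of EIF3C, U2AF1L5 and SMN1 had at most 115, 142 and 86 fragments in the control libraries and inhibitor library 1. The genes gained 666.3, 422.7 and 593.0, so a large loss was not possible there and its absence decides nothing. Fragments not counted for either were not examined, and NPIPB5, TBC1D3D, GATD3, LSM12P1 and SUDS3P1 were not tested in this way. For the pseudogenes DHFRP1 and SMG1P1 the copy lost at least 55.5% and up to 262%, so a move cannot be told apart from separate changes, and no biological explanation was tested.

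Genes with a miR-7 site had a slightly higher median change with the inhibitor. A trend over 3' UTR sequences of any kind is a candidate explanation, since 43.3% of 7-base words lay as far from 0 as the miR-7 site, ranked on the mean difference from matched genes in units of its SE. That mean was 0.0040 for the 7-base site (z = 2.01), and the rank depended on the pair of libraries: 0.65% of 7-base words were as high for the first inhibitor and control libraries and 51.54% for the second. Release of transcripts with the site stays open and cannot be told apart from it, as 2.47% of 8-base words were as high as the 8-base site and 20.02% of 7-base words as high as the 7-base site.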
